A study of Mus musculus with 8 samples.

How the data were processed

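RNA from ileal tumours was measured on 8 arrays of Illumina BeadChips, 4 of tumours from mice carrying the VP16 control transgene and 4 of tumours from mice carrying VP16LXRa, all on the APCmin/+ background, in a mixed C57BL/6J-FVBN strain and 8 months old, per the labels. The labels describe total RNA and biotinylated cRNA. They name no sex, chip, hybridisation batch or pairing, and the replicate numbers of the 2 groups do not overlap. The type of BeadChip and the release of its probe annotation are not given in the sources used here. Where nothing states that each array is a separate animal, p-values measure the spread between these samples.

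The deposited table of scanner values holds, for 25697 probes, an average bead signal, which is an intensity on a linear scale, and a detection p-value against the negative control beads of the same array, per the file headers. GenomeStudio was used, per the submitters' processing notes, with no version stated. The headers and values show no background subtraction or normalization in these intensities. The second table holds the authors' processed intensity values of the same arrays. From its values these were background-subtracted and quantile-normalized on a linear scale, with between 5897 and 5985 values below 0 per array and medians between 20.1 and 20.4. Each of its columns ranked the probes as the scanner signal of the same array did, with a Spearman correlation of 1. It was used as an alternative, with values under 16 set to 16 before log2, a floor chosen after the table was seen. No column of per-sample values was left unused.

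Gene symbols were those of the deposited table. Symbols of 32 probes that had been turned into dates or numbers were restored from the probe definitions. Against the RefSeq gene names of GRCm38.p6, 20736 probes matched by symbol, 3871 through a synonym and 1090 not at all. The files name no genome build, so chromosomes are those of the deposited table and no coordinates are given.

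The background was corrected with limma (version 3.58.1, R 4.3.3, with statmod 1.5.0) by normexp with negative controls inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. Probes with a detection p under 0.05 on at least 4 of the 8 arrays were tested, which left 13426 probes of 10056 genes. The groups were compared with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All differences are VP16LXRa minus control. Where a probe was not detected on any array of a group, its fold is a bound, taken from the bright group's mean against, per array, the higher of the probe's own value and the lowest value among detected probes.

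Gene lists were fixed before the data were examined, as were the test, the lists' test and the rule for named genes. Each gene was represented by its tested probe with the highest mean over all arrays. The 35 lists with at least 3 tested members were tested by camera with a preset inter-gene correlation of 0.01, with adjustment over the lists. A list's score in an array is the mean over its members of the log2 deviation from the 8-array mean. The genes named are Nr1h3, Nr1h2 and the LXR target list members past the threshold, with a summary of the others, and, since none passed, the 4 members with the smallest p and the 2 with the highest mean; genes past the threshold, or, where fewer than 3 passed in a direction, the 10 with the smallest p in that direction; and, for each list described, its members past the threshold or otherwise the 2 with the highest mean. Genes outside this rule are named as chosen after their values were seen.

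The steps were tested on simulated data with the spread of the real probes and 200 of 13426 probes changed. Of 50 probes changed by a log2 difference of 1, 8 were recovered, of 50 changed by 2, 37, of 50 changed by 3, 44, and of 50 changed by 4, 46, with 5 false calls. The simulated probes were drawn independently, and the 140 calls in all eased the adjusted threshold. With few or no calls that threshold is stricter, so these shares overstate the recovery of a lone changed probe. In simulated lists of independent genes, a list shifted by 1 had a camera adjusted p of 1.01e-06 with the preset correlation. With an estimated correlation it was 0.182, so for independent genes the second test is the less sensitive. The real lists were not independent, with estimated correlations of 0.747 for smooth muscle, 0.783 for erythroid and 0.200 for cholesterol genes. The simulation therefore does not show how either test behaves on them.

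Alternatives covered the background correction, the offset, the normalization, the filter, array weights, the variance prior, a term for high or low Eif2s3y (planned as a sex term), each array left out, thresholds, a minimum fold, set tests and the choice of probe. A BeadChip block was planned and not run, since the files give no chip. The number of arrays limits the precision.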

Results

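Gene expression was measured in ileal tumours of mice heterozygous for the Apc Min mutation, which develop intestinal tumours. The 4 VP16LXRa tumours came from mice carrying liver X receptor alpha (LXRα, a sterol-activated nuclear receptor) fused to VP16, a viral transactivation domain. The 4 control tumours came from mice carrying VP16 alone. Between 49.0% and 54.7% of the 25697 probes were detected per array, and the median signal ranged from 134 to 165. The median correlation of an array with the others was 0.869 for VP16LXRa 5 and between 0.910 and 0.942 for the other 7.

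The first question was whether tumours with the activated receptor differed in the receptor itself and in its targets. Nr1h3, which encodes LXRα, had a log2 level of 9.81 ± 0.73 (SD, n = 4) in control and 10.10 ± 0.32 (SD, n = 4) in VP16LXRa tumours, a difference of 0.28 (SE 0.37, adjusted p = 0.998). Without control 4 that difference was -0.0030. A second, dimmer Nr1h3 probe differed by 0.49. Nr1h2, the gene of LXRβ, differed by 0.05 (SE 0.23, adjusted p = 0.998), with a second probe at -0.57, or 0.086 without VP16LXRa 5. Whether any of these probes can detect the transgene's transcript is not given in the sources used here.

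Of the 19 LXR target genes tested, 11 were higher and 8 lower in VP16LXRa tumours, with a median log2 difference of 0.12. No member passed the threshold, either over all probes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Scd1, the stearoyl-CoA desaturase, was at 10.61 ± 2.05 (SD, n = 4) in control and 12.84 ± 1.09 (SD, n = 4) in VP16LXRa tumours, a difference of 2.23 (SE 0.95, adjusted p = 0.998). Abcg8, which forms a sterol efflux transporter with Abcg5, differed by 1.39 (SE 0.66), Srebf1, a regulator of fatty acid synthesis, by 1.34 (SE 0.68) and Arl4c by -1.06 (SE 0.53). Leaving out single arrays, Scd1 differed by 1.37 (without control 3) to 3.06 (without control 4), Abcg8 by 0.72 (without control 1) to 1.75 (without control 2) and Srebf1 by 0.87 (without control 1) to 1.82 (without control 4). Eif2s3y, a Y-linked gene, was high in 3 controls and 1 VP16LXRa array. With a term for high or low Eif2s3y, Scd1 differed by 0.95, Abcg8 by 1.13, Srebf1 by 0.40, Arl4c by -1.70, Abcg5 by 0.37 and Lpcat3 by -0.95. That term compares VP16LXRa 5 with controls 1 to 3, and VP16LXRa 6 to 8 with control 4, in equal parts. Its values therefore rest largely on the single arrays VP16LXRa 5 and control 4. The brightest members were Abcg5, which differed by 0.77 (SE 0.54; 0.33 without control 1 and 1.17 without VP16LXRa 5), and Lpcat3, a phospholipid-remodelling enzyme, by -0.03 (SE 0.74), with another probe at 0.24. Lpcat3 was at 10.01 in VP16LXRa 5 and between 13.02 and 13.67 in the other VP16LXRa arrays. Leaving out single arrays, Lpcat3 differed by -0.40 to 0.83 (without VP16LXRa 5). Its other probe differed by -0.11 (without VP16LXRa 8) to 1.10 (without VP16LXRa 5). The members not named here differed by between -0.35 and 0.41, and Abca1, detected on 1 array, was not tested. The list was not past the threshold (camera adjusted p = 0.402, and adjusted p = 0.737 with an estimated correlation). Without VP16LXRa 5 its median was 0.29 and its camera adjusted p with the preset correlation was 0.0138. In that setting 17 lists passed, against 9 with all arrays, and an estimated correlation was not tried there.

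**Figure D1:**
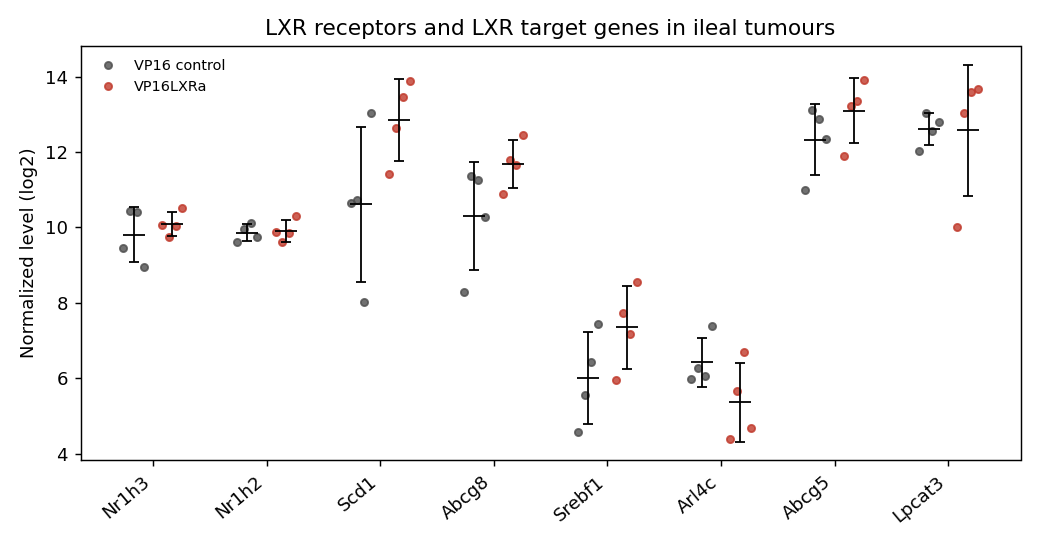
Normalized log2 level (vertical axis) of the LXR receptor genes and of 6 LXR target genes in each array, with points for the 4 control and 4 VP16LXRa tumours and bars for the mean and SD. The groups overlap for each gene shown, and Scd1 has the largest difference in means, 2.23.

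Across the array, 0 of 13426 probes passed the adjusted threshold with limma. At an unadjusted p under 0.05 there were 340 probes, 231 higher and 109 lower in VP16LXRa tumours, where 671 would be expected by chance. The 2 groups did not overlap for 233 probes, and chance gives 2.86% of probes without overlap. The smallest adjusted p was that of Tor1aip2, at 5.25 ± 0.58 (SD, n = 4) in control and 8.43 ± 0.46 (SD, n = 4) in VP16LXRa tumours, a difference of 3.18 (SE 0.34, adjusted p = 0.0795). It was detected on 2 of 4 control arrays and all 4 VP16LXRa arrays. Another tested probe, labelled Ifrg15 and counted with this gene through a synonym, differed by 0.02. The other probe labelled Tor1aip2 was detected on 2 arrays and not tested. Without control 3, the adjusted p of the first probe was 0.0298 with limma. With array weights and all 8 arrays, the first probe had an adjusted p of 0.0140 with limma, at a difference of 3.10. Over the alternatives in which it was tested, its difference ranged from 1.59 to 3.89.

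None of the other genes with the smallest p passed. Those higher in VP16LXRa tumours were Mcm6, a replication helicase subunit (3.04, SE 0.51), H19, an imprinted non-coding RNA (4.04, SE 0.69), Otof (3.94, SE 0.71), Gkn1, a gastric mucosal protein (5.10, SE 0.97), 5730469M10Rik (1.70, SE 0.34), Csrp1 (4.43, SE 0.95), Cops8 (2.43, SE 0.54), Nrcam (1.77, SE 0.40) and Lipf, gastric lipase (4.67, SE 1.07). Other tested Mcm6 probes differed by -0.33 and 0.26. H19, Otof and Nrcam were each detected on 1 of 4 control arrays, Gkn1, Lipf and Mcm6 on 2 and Csrp1 on 3. Sizes depended on the processing, from 1.56 to 3.77 for Mcm6, 2.22 to 4.55 for H19 and 0.64 to 2.12 for Nrcam over the alternatives. Without VP16LXRa 5, Mcm6 (adjusted p = 0.00444) and Csrp1 (adjusted p = 0.0484) passed. With array weights and all 8 arrays, Mcm6 passed at 3.58 (adjusted p = 0.0140 with limma). Without VP16LXRa 8, S100g, chosen after its values were seen, was the only probe to pass, at 4.06 (adjusted p = 0.0140).

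Those lower in VP16LXRa tumours were H2afj (-1.53, SE 0.37), H2-D4 (-1.29, SE 0.33), Myo1c (-0.85, SE 0.22), Cxcl10, an interferon-induced chemokine (-0.98, SE 0.26), Depdc6 (-0.84, SE 0.24), Ccdc97 (-0.78, SE 0.23), 2810022L02Rik (-0.96, SE 0.29), Greb1 (-0.84, SE 0.26), Ccdc53 (-1.09, SE 0.33) and Phf21a (-0.68, SE 0.21). Phf21a was not detected on any VP16LXRa array and, with the background correction used here, was at least 1.41-fold lower there (adjusted p = 0.998 with limma). That bound holds for this processing only. Over the alternatives the log2 difference of Phf21a ranged from -0.99 to -0.19, the latter without background correction. Of the 4 VP16LXRa arrays, Depdc6 was detected on 1, H2afj, Cxcl10 and Greb1 on 2, and H2-D4, Myo1c and 2810022L02Rik on 3, so these differences are imprecise. They also depended on the processing. Over the alternatives they ranged from -1.88 to -0.57 for H2afj, -1.61 to -0.47 for H2-D4 and -1.21 to -0.29 for Myo1c. The ranges were -1.29 to -0.31 for Cxcl10, -1.02 to -0.27 for Depdc6 and -1.22 to -0.28 for Greb1. Other probes differed by 0.11 and -0.32 for Myo1c, by 0.28 for Depdc6, by -0.35 and -0.57 for 2810022L02Rik and by -0.13 for Greb1. For Ccdc53 they differed by -0.60 and 0.06.

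Of the 35 gene lists, 9 passed camera with the preset correlation, 5 higher and 4 lower in VP16LXRa tumours, and 0 passed with an estimated correlation or with fry. No member of these 9 lists passed over all probes or adjusted over the list alone. Of the 35 splits of the arrays into 4 and 4, 32 gave at least 9 lists, the real split included. With the Eif2s3y term, which rests largely on VP16LXRa 5 and control 4, 3 lists passed. These were the smooth muscle markers, which are among the 9, absorptive enterocyte markers (median 0.73, adjusted p = 0.0433) and intestinal stem cell markers (median -0.53, adjusted p = 0.0303), which are not. Over all alternatives, adjusted p ranged from 0.000211 to 0.923 for the enterocyte list and from 0.00827 to 0.984 for the stem cell list. With that term the medians of the other lists among the 9 were 0.38 (Paneth), 1.38 (erythroid), 0.31 (fibroblast), 0.27 (endothelial), 0.053 (interferon), -0.090 (MHC class II), -0.59 (B cell) and 0.040 (cholesterol), and that of the smooth muscle markers was 1.17.

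Markers of stroma and vessels were higher. All 13 tested smooth muscle markers were higher, with a median log2 difference of 1.04 (camera adjusted p = 9.25e-06, and adjusted p = 0.737 with an estimated correlation). Acta2, smooth muscle actin, differed by 1.04 (SE 0.83), with other probes at -0.20, -0.16 and 1.18 (the first 2 at 1.25 without VP16LXRa 5), and Actg2 by 1.56 (SE 1.02). Their mean score was -2.65 in control 3 and between -0.50 and 0.92 in the other 7 arrays, and without control 3 the median was 0.36, with Acta2 at 0.051 and Actg2 at 0.33. Of 21 fibroblast and matrix genes, 16 were higher, with a median of 0.44 (adjusted p = 0.025, and 0.737 as the adjusted p with an estimated correlation). Dcn differed by 0.60 (SE 0.64), with another probe at 0.17 (-0.57 without control 3), and Bgn by 0.21 (SE 0.69). Without control 3 the fibroblast median was -0.0078. Of 15 endothelial markers, 12 were higher, with a median of 0.47 (adjusted p = 0.0299, and 0.737 as the adjusted p with an estimated correlation). Gp38 (podoplanin) differed by 1.26 (SE 0.76) and Plvap by -0.29 (SE 0.58). The fibroblast median was 0.23 without VP16LXRa 5 and 0.69 without control 4, and the endothelial median 0.18 without control 3, 0.25 without VP16LXRa 5 and 0.30 without VP16LXRa 7. The fibroblast call ended without control 3, VP16LXRa 5 or VP16LXRa 6, and the endothelial call without any of these or VP16LXRa 7, or with all probes.

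Paneth cell and erythroid markers were also higher. Of 15 Paneth markers, 13 were higher, with a median of 0.96 (camera adjusted p = 0.00486, and adjusted p = 0.737 with an estimated correlation). Lyz, lysozyme, differed by 0.44 (SE 0.54), with other probes at -0.67 (1.40 without VP16LXRa 5) and 0.74, and Defcr20, an antimicrobial α-defensin, by 0.75 (SE 0.67), with another probe at -0.31 (1.63 without VP16LXRa 7). Without control 1 the Defcr20 difference was 0.094. The α-defensins are a family of near-identical genes, so their probes may share targets. Without the α-defensins the list's median was 0.44 and its adjusted p was 0.316. List members with the largest differences, Defcr-rs7 (5.44) and Defcr-rs10 (5.01), chosen after their values were seen, were each on in some arrays and off in others. The Paneth call also ended without control 1 (median 0.32), control 2 (0.74), VP16LXRa 6 (0.54) or VP16LXRa 8 (0.73). All 4 tested erythroid markers were higher, with a median of 1.65 (camera adjusted p = 0.00486, and adjusted p = 0.737 with an estimated correlation). Hba-a1 and Hbb-b1, globin genes, differed by 1.81 (SE 1.06) and 1.30 (SE 0.86). The erythroid score was -1.47 in VP16LXRa 8 and between 1.43 and 1.82 in the other 3 VP16LXRa tumours, and the call ended without VP16LXRa 6 or VP16LXRa 7. Over the alternatives the erythroid median ranged from 0.50 to 2.46.

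The immune lists that passed, 3 in all, were lower. Neutrophil and mast cell markers did not pass, with 7 of 10 higher and a median of 0.27. Of 24 interferon response genes, 23 were lower, with a median of -0.41 (camera adjusted p = 0.000708, and adjusted p = 0.737 with an estimated correlation). Irf1 differed by -0.13 (SE 0.24) and Irgm1 by -0.02 (SE 0.25). Other Irf1 probes differed by -0.46, -0.14, -0.57 and -0.48, and another Irgm1 probe by -0.40. Without VP16LXRa 5, the Irf1 probes at -0.46, -0.57 and -0.48 were at 0.015, 0.021 and 0.044. The interferon score was -0.85 in control 4 and between 0.44 and 0.57 in the other 3 controls. The interferon median was -0.74 without control 4, -0.25 without control 1, -0.24 without control 2, -0.18 without control 3 and -0.27 without VP16LXRa 5, past the threshold each time. Of 8 MHC class II genes, 6 were lower, with a median of -0.41 (adjusted p = 0.0159, and 0.737 as the adjusted p with an estimated correlation). Cd74 differed by -0.28 (SE 0.30), with another probe at 0.069, and H2-Ab1 by 0.0036 (SE 0.44), with other H2-Ab1 probes at -1.76 (-0.028 without VP16LXRa 5) and -0.36. Of 10 B and plasma cell markers, 8 were lower, with a median of -0.76 (adjusted p = 0.0159, and 0.737 as the adjusted p with an estimated correlation). Cd79b differed by -1.58 (SE 0.96) and 2010001M09Rik, which encodes Mzb1, by -0.84 (SE 0.63). The B cell score was 2.50 in control 2 and between -0.88 and 0.26 in the other 7 arrays, and without control 2 the median was -0.12, with Cd79b at -0.58 and 2010001M09Rik at -0.26. Control 2 also had the highest MHC class II (1.26), T cell (1.25) and macrophage and dendritic cell (0.64) scores of all arrays. The MHC class II median was -0.72 without control 4, -0.18 without control 2 and -0.22 without control 3. The MHC class II call ended without control 2, control 3, VP16LXRa 6 or VP16LXRa 7, and the B cell call without control 2, control 4, VP16LXRa 7 or VP16LXRa 8, or with probes detected on all 8 arrays.

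Cholesterol synthesis and uptake genes were slightly lower. Of 21 tested, 15 were lower, with a median of -0.09 and a mean of -0.22 (camera adjusted p = 0.0299, and adjusted p = 0.737 with an estimated correlation). Fdps differed by -0.07 (SE 0.29) and Sc4mol by -0.12 (SE 0.33). Their score was 0.54 in control 3 and between -0.16 and 0.04 in the other 7 arrays, and the call ended without control 3 (median -0.017), VP16LXRa 6 (-0.057) or VP16LXRa 8 (-0.030). The median was -0.17 without control 1, -0.18 without control 2, -0.24 without control 4 and -0.14 without VP16LXRa 5. The call also ended with array weights, with probes detected on all 8 arrays and with the mean over probes. The other 26 lists had adjusted p-values from 0.0767 to 0.810 and medians from -0.28 to 0.78.

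**Figure D2:**
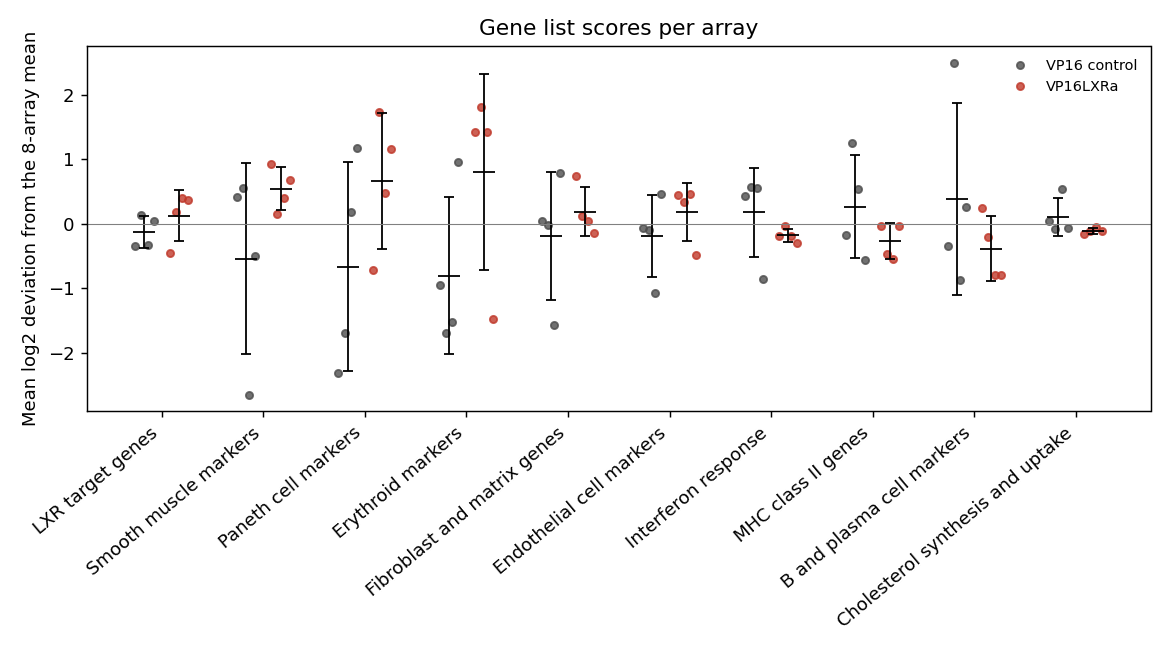
Score of each list (vertical axis, mean log2 deviation from the 8-array mean) in each of the 4 control and 4 VP16LXRa arrays, with bars for the mean and SD. The smooth muscle score of control 3, -2.65, and the B cell score of control 2, 2.50, lie far from the other arrays.

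The sex of the animals is not in the labels. Eif2s3y, a Y-linked gene, was between 9.37 and 9.86 in controls 1 to 3 and 9.81 in VP16LXRa 5, and between 4.83 and 5.90 in control 4 and the other 3 VP16LXRa arrays. The other 4 Y-linked genes tested did not follow it. Ddx3y was detected on all 8 arrays, between 10.87 and 11.72, with 11.54 in control 4, as were Uty, between 5.40 and 6.10, and Jarid1d, between 5.85 and 7.42. Rbmy1a1 was near the background, between 4.81 and 5.83; it and Jarid1d were chosen after their values were seen. Untested Ddx3y probes were detected on VP16LXRa 8 and on VP16LXRa 6 and 8. Of 2 Xist probes, 1 was detected on no array and the other on 1. The Eif2s3y term was planned as a term for sex, and from these genes it cannot be taken as one.

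**Figure D3:**
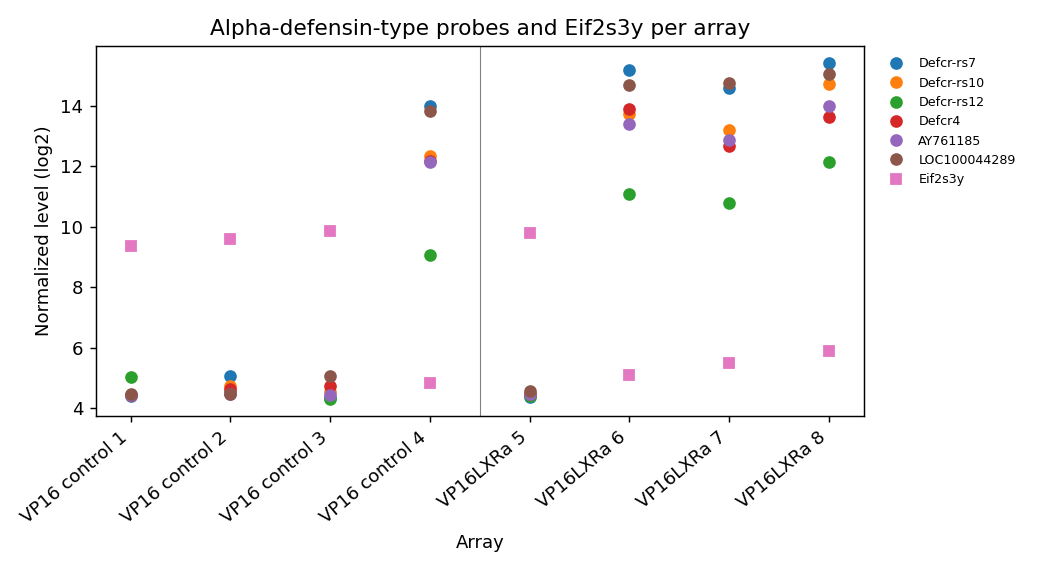
Normalized log2 level (vertical axis) of 6 α-defensin-type probes (circles) and Eif2s3y (squares) in each array, controls left of the line and VP16LXRa right. The 6 probes are at or below 5.08 in 4 arrays and at or above 9.07 in the other 4, where Eif2s3y is low; these probes were chosen after their values were seen.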

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

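All tests in this part were chosen after the results were seen, except that of the most enriched chromosome. Within the groups of 4, 122 sets of values were examined for a sample far from the others and 14 met the criterion, where chance gives about 6.1. A further 14 sets, from 7 probes chosen because they stood apart, are left out of that comparison, and 13 of these met it.

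VP16LXRa 5 lay apart. Its median correlation with the other arrays was 0.869, against 0.939 to 0.942 in the other VP16LXRa arrays, and the 90th percentile of the spread between probes of one gene was 2.40, against 0.603 to 0.819 in the other 7 arrays. The other 3 VP16LXRa arrays reached at most 0.794, below the highest control, which argues against the genotype. No cell type list in VP16LXRa 5 exceeded the next array by more than 0.439, against another tissue as the source. RNA quality or labelling of this sample may account for the disagreement between probes, and it stays a hypothesis.

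The probes Defcr-rs7, Defcr-rs10, Defcr-rs12, Defcr4, AY761185 and LOC100044289 were off in 3 controls and on in control 4, at 13.98, 12.36, 9.07, 12.18, 12.13 and 13.84, and off in VP16LXRa 5 alone of its group, where all but Defcr-rs12 met the criterion, at 4.37, 4.45, 4.48, 4.49 and 4.56; Eif2s3y was opposite, at 4.83 in control 4 and 9.81 in VP16LXRa 5. Where off, the 6 lay below the lowest array with them on by a median of at least 7.63 and the other 14 α-defensin probes by at most 2.48 (control 1), with medians above it in control 3 and VP16LXRa 5, which argues against a smaller share of Paneth cells as the whole cause. The other Y-linked genes tested, 4 of 4, were detected on every array with low Eif2s3y (Ddx3y at 11.16 or more). None was lower on each of these arrays than on the others. Rbmy1a1 (at most 5.83) and Uty (at most 6.10) lay near the background, and 2 further Ddx3y probes were undetected wherever Eif2s3y was high. Binding to X-linked relatives was not tested, so these genes leave sex open. A strain variant was left open, with 0 values of the 6 probes between 6 and 8. Of the 6, 2 were placed on chromosome 8 and 4 had no chromosome. An exchange of the labels of VP16LXRa 5 and control 4 would only regroup the arrays, and would not by itself turn the 6 probes on or off. Whether the labels were exchanged was also left open. Outside these 7 probes, the split with both labels exchanged gave 950 probes at an unadjusted p under 0.05. That number was reached by 6 of the 35 splits, with 1970 the highest.

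Chromosome 1, which holds Tor1aip2, Mcm6 and Cops8, gave 12 of the 100 probes with the smallest p, a number that 1 of 35 splits reached, with 11 the highest of the others. Taking whichever chromosome was most enriched, 5 of 35 splits were enriched as strongly. The 12 other tested probes of these chromosome 1 genes differed both ways, by a median of 0.275 in the direction of the first probe, against -0.0971 to 1.68 in the other splits with such probes. For Mcm6, the other tested probes, at -0.33 and 0.26, did not share the 3.04 of the first. Across the chromosome 1 genes the median of the other probes lay within the range of the other splits. Chromosome 1 was also singled out after it was seen. A segment or probe variant carried with the transgene and a change of whole transcripts therefore cannot be told apart for these genes as a set.

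Chance cannot be excluded for the counts. Every split, 35 of 35, must reach the real count of 0 probes past the adjusted threshold with limma, so that count tests nothing; the highest of the others was 12. Of the 35, 26 gave as many as the real 340 probes at an unadjusted p under 0.05, with 1970 the highest. For lists, 32 splits gave at least 9, with 21 the highest. For the LXR target list 17 splits gave an absolute median as large as 0.12, with 0.46 the highest. Splits that call several times the real count may point to a structure of the samples other than the labels, which was not tested.

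Single samples also stood apart in these values. Control 4 had 52.8% of probes detected, a median correlation of 0.910, an interferon score of -0.85, H19 at 6.03 and Irf1 at 12.76. Control 3 had Otof at 6.42, Acta2 at 10.24 and Actg2 at 8.27. VP16LXRa 8 had an erythroid score of -1.47, an endothelial score of -0.48 and Hba-a1 at 10.08. VP16LXRa 6 had 2010001M09Rik at 10.83.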

How the results depend on the processing

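The settings without VP16LXRa 5 and control 4 together, the Paneth list without α-defensins, the floor of 16 and the exact permutation of list scores were chosen after seeing the data. The number of probes past the threshold was 2 with array weights, 2 without VP16LXRa 5 and control 4, 1 at an adjusted p under 0.1 and 0 to 2 when leaving out each array. It was 0 in the other alternatives run, with 146 to 1191 probes at an unadjusted p under 0.05. Without VP16LXRa 5 and control 4, the 2 probes were Mcm6 (3.77) and Eif2s3y (-4.13). Leaving out these arrays leaves Eif2s3y high in every remaining control and low in every remaining VP16LXRa array. Its passing was fixed by that choice and tests nothing. The number of lists past the threshold was 15 with array weights, 3 with the term for high or low Eif2s3y, 14 without both arrays, 0 with an estimated correlation, 0 with either form of fry, 0 with the exact permutation and 3 to 17 when leaving out each array. The exact permutation p cannot fall below 0.0286 with these arrays, so passing after adjustment over the lists was hardly possible. Its smallest value before adjustment was 0.0857. The LXR target median was -0.013 with all probes and 0.028 to 0.29 when leaving out each array. With the Eif2s3y term, values turned for the interferon list (0.053), the cholesterol list (0.040), Lyz (-0.033), Irf1 (0.12), Irgm1 (0.19) and Sc4mol (0.28). With array weights they turned for Lpcat3 (0.60), Nr1h2 (-0.015), Plvap (0.11), H2-Ab1 (-0.27) and Fdps (0.016), without normalization for Nr1h2 (-0.014) and H2-Ab1 (-0.025), and without both arrays for Lpcat3 (0.89), Plvap (0.44) and H2-Ab1 (-0.46). Among lists not past the threshold whose medians are given, the Eif2s3y term turned Wnt targets (-0.10), cell cycle (-0.038) and neutrophil and mast cell markers (-0.053). All probes turned Wnt targets (-0.011), probes on all 8 arrays stem cell markers (0.018), array weights stem cell markers (0.18), and no normalization cell cycle (-0.0025). Leaving out both arrays turned stem cell (0.42), enterocyte (-0.042) and tuft cell (-0.082) markers. Leaving out each array gave ranges that cross 0 for Wnt targets (-0.0027 to 0.49), cell cycle (-0.034 to 0.29), stem cell (-0.32 to 0.44), enterocyte (-0.085 to 0.70), tuft cell (-0.14 to 0.24) and neutrophil (-0.14 to 0.61) markers and fatty acid oxidation (-0.032 to 0.32). Leaving out each array gave ranges that cross 0 for Nr1h3 (-0.0030 to 0.49), Nr1h2 (-0.078 to 0.15), Lyz (-0.088 to 0.73), Irgm1 (-0.22 to 0.14), H2-Ab1 (-0.32 to 0.25), Lpcat3 (-0.40 to 0.83), Plvap (-0.78 to 0.15), Fdps (-0.22 to 0.17), Sc4mol (-0.33 to 0.12), Dcn (-0.075 to 1.10), Bgn (-0.48 to 0.64) and the fibroblast list (-0.0078 to 0.69). Within 1 direction, ranges were wide for Acta2 (0.051 to 1.43), Actg2 (0.33 to 2.10), Defcr20 (0.094 to 1.14), Gp38 (0.74 to 1.86), Hbb-b1 (0.79 to 2.01), Cd79b (-2.19 to -0.58), 2010001M09Rik (-1.33 to -0.26), Cd74 (-0.45 to -0.10) and Irf1 (-0.32 to -0.054). The cause was not tested. The planned BeadChip block was not run. Genes near the background are measured less precisely, since probes are detected on only some arrays.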

Other observations

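The gastric and the imprinted list were both written after the data were examined, and the gastric test was chosen after the result was seen.

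In 2 lists a member passed when adjusted over the list alone. Each of the 35 lists was adjusted on its own, with no adjustment across lists, so chance alone may give such members. Ppargc1a, a coactivator of mitochondrial genes, was higher in VP16LXRa tumours by 1.38 (SE 0.33, adjusted p = 0.0413 over the fatty acid oxidation list alone and 0.998 over all probes with limma). Trpm5, a tuft cell channel, was higher by 1.34 (SE 0.35, adjusted p = 0.0305 over the tuft cell list alone and 0.998 over all probes). Neither list passed as a whole, with medians of 0.24 and 0.15. Wnt target genes had a median of 0.12, cell cycle genes 0.03, intestinal stem cell markers -0.16 and absorptive enterocyte markers 0.36, none past the threshold. They depended on the settings. Without control 4 the medians were 0.49, 0.29, 0.44 and -0.085, and the first 3 passed camera with the preset correlation, as did those below. An estimated correlation was tried on all 8 arrays alone, where no list passed. With array weights and all 8 arrays, the Wnt (0.25) and cell cycle (0.23) lists passed. The enterocyte list passed without control 2 (0.67), control 3 (0.70) or VP16LXRa 5 (0.31), and the fatty acid oxidation list without control 1 (0.31) or VP16LXRa 5 (0.32).

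Gkn1 and Lipf are gastric genes, and 5 further gastric genes were tested as a group. All 5 were higher, with a score of -0.65 ± 1.28 (SD, n = 4) in control and 0.65 ± 1.93 (SD, n = 4) in VP16LXRa tumours, and an exact two-sided permutation p of 0.229. The score was 2.41 and 2.15 in VP16LXRa 6 and 7, 1.15 in control 4, -0.47 in VP16LXRa 5 and -1.50 in VP16LXRa 8. Gkn1 and Lipf were at 12.45 and 10.20 in VP16LXRa 5 and at 8.08 and 9.89 in VP16LXRa 8, so they did not follow the score there. In VP16LXRa 6 and 7 they were high together with the score. Gastric-type epithelium in VP16LXRa tumours may contribute, and these 8 arrays leave that open.

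H19 is imprinted, and 8 other imprinted growth genes were tested to see whether the group moved. Of these 7 were higher. Gnas, named after its values were seen, was lower through 1 array, at 5.13 in VP16LXRa 5 and 9.93 to 10.16 in the other 3 VP16LXRa arrays, against 9.51 to 10.36 in control. The group had a difference in score of 0.47 and an exact two-sided permutation p of 0.314. The group was not shown to differ.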
